A study of Homo sapiens with 6 samples.

How the data were processed

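Polyadenylated RNA was sequenced from H1 human embryonic stem cells that carry DUX4, a transcription factor of early embryonic genome activation, under a doxycycline-inducible promoter. Per the labels' protocols, cells grown in mTeSR medium on a Matrigel-type coating were first transfected with antisense oligonucleotides (ASOs), short nucleic acids that direct the degradation of matching RNA. The ASOs were either a mix against the MLT2A1 subfamily or a control. MLT2A1 is a long terminal repeat (LTR) of the endogenous retrovirus family ERVL. Doxycycline was added 24 h later at 1 µg/ml, and total RNA was extracted with Trizol 24 h after that. Libraries were made with a NEBNext kit that selects polyadenylated RNA and does not keep the strand, so reads from a gene and an overlapping antisense gene cannot be told apart. The 6 libraries form 3 groups of 2: hESC_Ctrl_KD (control ASO, no doxycycline), DUX4OE_Ctrl_KD (control ASO, DUX4 induced) and DUX4OE_MLT2A1_KD (MLT2A1 ASO mix, DUX4 induced). Groups came from the sample titles. The columns of the deposited tables were matched to samples by name, and every column had a sample. Those of the uninduced control carry the name shNC, although the labels describe an ASO control.

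The authors deposited raw read counts per gene and per repeat subfamily, and a second table of TPM, a length-scaled relative abundance, for the same features. Per the submitters' processing notes, FastQC 0.11.9, cutadapt 4.1, STAR 2.7.10a, featureCounts 2.0.1 and edgeR 3.30.3 were used with the human genome build GRCh38 (hg38). The role of each tool, the annotation release, the treatment of reads that map to several places and the strand setting are not given in the sources used here. Per the file headers, each library was counted on its own. The count table has 60642 gene features and 1180 repeat subfamilies, the latter named after RepeatMasker annotation. The deposited TPM values sum to the same total in each library over genes and repeats together, so a change in the share of repeat reads changes the TPM of genes. The name of 1 gene in the TPM table had been altered in the form of a date, and it was restored from its place beside the count table, in which all other names stood in the same order. How reads shared among near-identical copies were counted is not known, and values of multicopy families such as DUX4, PRAMEF, TRIM49 and TRIM64, and of single repeat subfamilies, are uncertain for that reason.

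Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood F tests on all 6 libraries in one model with a mean per group, which leaves 3 residual degrees of freedom. Library sizes and TMM factors were taken from gene features only. Features were filtered with filterByExpr, which left 35375 genes and 1173 repeat subfamilies. Benjamini-Hochberg adjustment was applied over genes and over repeats separately, with calls at an adjusted p under 0.05. CPM values are read counts scaled to the effective library size, and errors are standard deviations (SD) over the 2 libraries of a group or standard errors (SE) of the log2 fold change. The SE was taken as the absolute log2 fold change divided by the square root of the F statistic. It is approximate, and may be too small for genes with few reads in a group, such as DUX4 and DBET. Fold changes of genes with no read in a group are given as lower bounds, against a floor of 3 counts over that group's libraries. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. The comparisons were DUX4OE_MLT2A1_KD with DUX4OE_Ctrl_KD, which the series design names, DUX4OE_Ctrl_KD with hESC_Ctrl_KD, and DUX4OE_MLT2A1_KD with hESC_Ctrl_KD.

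Before the data were examined, 22 gene lists and 11 repeat lists were fixed, together with the tests, the alternatives and the rule for naming genes. The gene lists cover DUX4 and 8-cell-stage genes, core and primed pluripotency, naive pluripotency, oocyte and maternal genes, trophoblast, amnion, hypoblast and endoderm, mesoderm, neural and ectoderm, fibroblast and stromal genes, p53 targets, interferon response, integrated stress and unfolded protein response, heat shock and immediate early genes, cytosolic ribosomal proteins, mitochondrially encoded genes, replication-dependent histones, S phase, G2 and mitosis, spliceosome and hnRNP genes, nonsense-mediated decay and retroelement silencing. The repeat lists cover MLT2 LTRs, the pair MLT2A1 and MLT2A2, ERVL internal parts, HERVH and LTR7, HERVK and LTR5, THE1 and MST elements, LTR12, young L1, AluY, SVA and satellites. Lists with at least 5 tested genes or 3 tested repeats were compared with all other tested genes or repeats by camera in limma 3.58.1, with a preset correlation of 0.01 between genes, and again with an estimated correlation. Named genes are DUX4, MLT2A1 and MLT2A2. They also include the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 CPM and no overlap between the groups, with clone-based names and pseudogenes passed over, and the 5 largest of each direction among repeats. The rule adds the 4 members with the smallest p of each called list, up to 2 of any other list discussed, members of the repeat lists, and the 8 genes with the largest opposite changes in both comparisons. Any other named gene is said to be chosen after its values were seen. Gene coordinates come from GENCODE 29 on GRCh38, 1-based, and may differ from the release the authors used.

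The fits were tested on simulated counts for the real genes and library sizes, with 200 genes changed by known folds. For the knockdown comparison (31432 genes fitted), edgeR recovered 77.6% of 67 genes changed 2-fold, 97.0% of 67 changed 4-fold and 98.5% of 66 changed 8-fold, with 3 false calls. For DUX4 induction (31419 genes fitted) the shares were 85.1%, 95.5% and 98.5%, with 4 false calls. With p53 targets raised 2-fold in the simulated knockdown comparison, camera called that list and 0 of the other lists, among 22 tested on 31392 genes. All other genes were simulated as unchanged and independent of each other. These simulations therefore do not test the scaling where most genes change, or camera where the genes of a list are correlated. The alternatives were DESeq2 1.42.0 with its own size factors, TMM over genes and repeats together, library sizes without TMM factors, no filter on low counts, at least 10 counts in 2 libraries, the replicate number as a block, only the 2 groups compared, limma on log2(TPM + 1) and log2(TPM + 0.1), a robust fit, an added minimum log2 fold change of 1, and leaving out each library in turn. The limma fits kept only features above a minimum mean TPM, so their counts come from another set of tested features. Chosen after seeing the data were TMM factors from the 12419 genes with a mean of at least 10 CPM over all libraries, a refit of only those genes and the 923 repeat subfamilies at that level, and, for the overlap of calls between comparisons, expected counts within 20 bins of level and a split of the DUX4OE_Ctrl_KD libraries.

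The 2 libraries of each group differed by more than sampling noise, with chi-square values per degree of freedom of 2.23, 11.7 and 6.23 for hESC_Ctrl_KD, DUX4OE_Ctrl_KD and DUX4OE_MLT2A1_KD. Nothing in the labels says whether they came from separate cultures, so p-values measure the spread between these libraries, which may be technical.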

Results

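Transcriptomes of H1 human embryonic stem cells were measured by polyadenylated RNA sequencing in 3 groups of 2 libraries each. DUX4 induction moves such cells towards a state that resembles the 8-cell embryo, in which DUX4 targets and ERVL elements are transcribed. The comparison named in the series design asks what knockdown of the MLT2A1 retroviral LTR subfamily changes in DUX4-induced cells. Read counts over genes and repeats totalled 52650205 and 50999316 in hESC_Ctrl_KD, 47558844 and 42859584 in DUX4OE_Ctrl_KD, and 46468264 and 45633447 in DUX4OE_MLT2A1_KD. Of these, 43215280, 41591317, 37454734, 33355187, 25781748 and 23666479 lay over genes, in that order. Repeats took 17.9% and 18.4% of counts in the uninduced control and 21.2% and 22.2% in the induced control. In the libraries labelled DUX4OE_MLT2A1_KD they took 44.5% and 48.1%.

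MLT2A1 was at 61.0 ± 0.117 CPM (SD, n = 2) in hESC_Ctrl_KD, 689 ± 132 CPM in DUX4OE_Ctrl_KD and 183 ± 19.2 CPM in DUX4OE_MLT2A1_KD. By library, these were 60.9 and 61.1, 596 and 782, and 169 and 197 CPM. The targeted subfamily was 3.77-fold lower in the libraries labelled DUX4OE_MLT2A1_KD than in the induced control (log2 fold change −1.91, SE 0.11, edgeR adjusted p = 5.18e-15), or −1.32 on the log2 scale with library sizes alone. Its relative MLT2A2 was at 153 ± 0.656, 444 ± 64.8 and 308 ± 31.8 CPM in the same order of groups. The change of MLT2A2 between the last of these groups was −0.53 (SE 0.10, adjusted p = 1.17e-05), but it lay at 0.06 and was not called with library sizes alone or with TMM factors from genes at 10 CPM or more. DUX4 itself went against the label of the knockdown libraries. It had 0 and 0 reads in hESC_Ctrl_KD, 12485 and 8816 in DUX4OE_Ctrl_KD, and only 8 and 13 in DUX4OE_MLT2A1_KD, although the latter were also labelled as induced. In CPM, DUX4 was at 348 ± 59.6 in the induced control and 0.330 ± 0.121 in the libraries labelled DUX4OE_MLT2A1_KD, 1049-fold lower (log2 fold change −10.03, SE 0.19, adjusted p = 2.15e-22). Summed over the 42 DUX4 and DUX4-like features, the counts were 7 and 7, 44510 and 32751, and 144 and 186. Each direction drawn from DUX4OE_MLT2A1_KD therefore holds for libraries that differed from the induced control in DUX4 as well as in MLT2A1. DUX4 lies on chromosome 4 at 190173774 to 190185942, in the subtelomeric repeat array, where near-identical copies can share reads. Reads of the inducible DUX4 construct may be counted there too, and cannot be told apart from those of the endogenous copies.

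**Figure D1:**
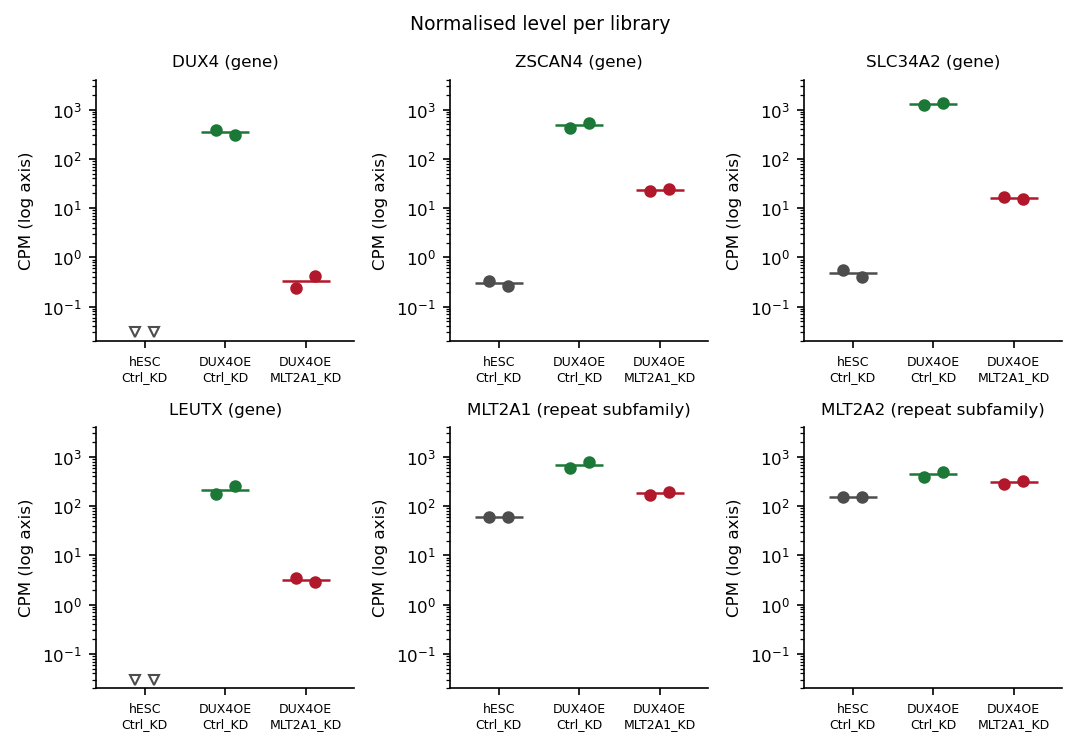
Normalised level (CPM, log axis) of 4 genes and 2 repeat subfamilies in each of the 6 libraries; points are libraries, horizontal lines are group means, and open triangles at the foot of the axis are libraries with 0 reads. DUX4 stood at 390 and 306 CPM in the induced control and at 0.244 and 0.416 CPM in the libraries labelled DUX4OE_MLT2A1_KD, while MLT2A1 stood at 596 and 782 against 169 and 197 CPM.

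In the libraries labelled DUX4OE_MLT2A1_KD, genes of the 8-cell stage were far lower than in DUX4OE_Ctrl_KD. Of 75 tested genes of the DUX4 and 8-cell-stage list, 66 fell, 5 rose and 4 were not called, with a median log2 fold change of −4.96 (camera adjusted p = 4.37e-22). With an estimated correlation between genes the adjusted p = 0.249. SLC34A2, a sodium-phosphate transporter on chromosome 4 at 25648011 to 25678748, fell from 1299 ± 84.0 to 16.4 ± 0.973 CPM (79.4-fold, log2 fold change −6.31, SE 0.11). The PRAME family members PRAMEF12 and PRAMEF1 fell by 5.86 (SE 0.11) and 5.98 (SE 0.12) on the log2 scale, and RFPL4B fell by 5.88 (SE 0.13). ZSCAN4, a zinc finger gene active in 8-cell embryos (chromosome 19, 57668935 to 57679152) and named here after its values were seen, fell 20.4-fold, from 477 ± 83.8 to 23.4 ± 1.97 CPM (log2 fold change −4.35, SE 0.12). The 5 that rose were TPRXL, ARGFX, PLAC8L1, RPL3L and GADD45A, also named after their values were seen. Their log2 fold changes were 4.47, 3.49, 2.03, 1.97 and 1.63. Summed over the list, the level was 338 CPM in hESC_Ctrl_KD, 10387 CPM in DUX4OE_Ctrl_KD and 553 CPM in DUX4OE_MLT2A1_KD. The last sum was 5.32% of that in the induced control.

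**Figure D2:**
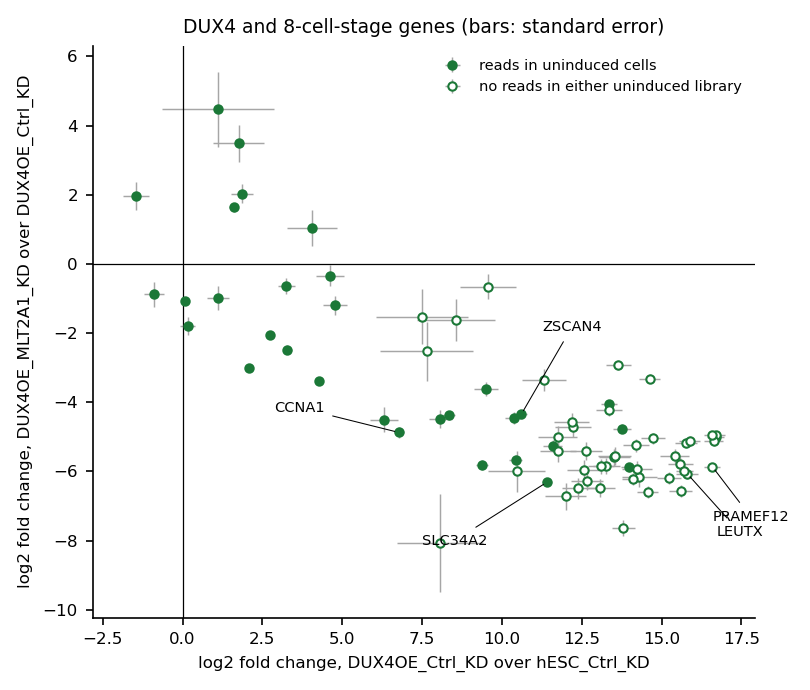
Log2 fold change of each tested gene of the DUX4 and 8-cell-stage list with DUX4 induction (horizontal axis) and between the libraries labelled DUX4OE_MLT2A1_KD and DUX4OE_Ctrl_KD (vertical axis), with standard errors. Open symbols have no read in either uninduced library, so their horizontal position depends on the model's prior count; 63 of the 69 genes that rose with induction fell in the vertical comparison.

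Target genes of the tumour suppressor p53 were higher in the libraries labelled DUX4OE_MLT2A1_KD. Of 32 tested, 26 rose, 4 fell and 2 were not called (median 0.83, camera adjusted p = 7.30e-06, and adjusted p = 0.0910 with an estimated correlation). MDM2, the ubiquitin ligase that limits p53 (chromosome 12, 68808176 to 68850686), rose from 177 ± 3.04 to 793 ± 44.6 CPM (log2 fold change 2.17, SE 0.09). BTG2, an antiproliferative gene on chromosome 1 at 203305491 to 203309602, rose from 4.15 ± 0.135 to 47.4 ± 2.09 CPM (3.51, SE 0.13). The DNA polymerase gene POLH and the death receptor gene FAS rose by 2.48 (SE 0.11) and 2.83 (SE 0.15). Replication-dependent histone genes also rose, 15 of 18 with 3 not called (median 1.96, adjusted p = 2.31e-05, and adjusted p = 0.140 with an estimated correlation). H4C14, H2BC21 and H4C8 rose by 2.87, 2.77 and 2.88 (SE 0.13, 0.15 and 0.16). Most of these histone RNAs lack a poly(A) tail.

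Proliferation genes were lower. Of 27 S phase genes 26 fell (median −1.04, camera adjusted p = 1.32e-10, and adjusted p = 0.0540 with an estimated correlation), as did 28 of 28 G2 and mitosis genes (median −1.02, adjusted p = 3.67e-11, and adjusted p = 0.230 with an estimated correlation). The ribonucleotide reductase subunit RRM2 fell from 277 ± 42.5 to 79.1 ± 7.40 CPM (−1.81, SE 0.10), and the mitotic kinase CDK1 from 171 ± 29.6 to 50.8 ± 4.25 CPM (−1.75, SE 0.10). CLSPN, MCM6 and CCNA2 fell by 1.62, 1.29 and 1.46. Fibroblast and stromal genes fell in 15 of 18 cases and rose in 2 (median −1.09, adjusted p = 2.31e-05, and adjusted p = 0.140 with an estimated correlation), with the collagen genes COL1A2 and COL5A1 at −2.02 (SE 0.09) and −2.70 (SE 0.13). With TMM factors from genes at 10 CPM or more, 19 S phase, 19 G2 and mitosis and 11 stromal genes were called lower. The medians were then −0.45, −0.43 and −0.50, and those of p53 targets and histones 1.42 and 2.55.

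Genes of 5 further lists were lower, by an amount and in a number that changed with the scaling and with the genes tested. They lay below all other genes with either scaling, but none of the 5 was called in a refit of only the genes at 10 CPM or more, where the adjusted p was 0.372 for ribosomal protein, 0.499 for core and primed pluripotency, 0.131 for spliceosome and hnRNP, 0.387 for stress response and 0.722 for retroelement silencing genes. With TMM factors from genes at 10 CPM or more and an estimated correlation, camera also called none of the 5. Its adjusted p was then 0.390 for ribosomal protein and 0.138 for spliceosome and hnRNP genes. It was 0.161 for core and primed pluripotency, stress response and retroelement silencing genes. Of 78 cytosolic ribosomal protein genes 76 fell (median −0.67, adjusted p = 1.10e-15, and adjusted p = 0.249 with an estimated correlation), while 12 fell and 4 rose with TMM factors from genes at 10 CPM or more (median −0.08). For the 41 core and primed pluripotency genes, 36 fell and 4 rose (median −0.71, adjusted p = 2.82e-08, and adjusted p = 0.226 with an estimated correlation), against 18 and 8 under that scaling (median −0.12). For the 39 spliceosome and hnRNP genes, 33 fell (median −0.78, adjusted p = 2.23e-10, and adjusted p = 0.0540 with an estimated correlation), against 20 lower and 9 higher (median −0.19). Of 31 genes of the integrated stress and unfolded protein response, 21 fell and 7 rose (median −0.64, adjusted p = 0.00188, and adjusted p = 0.140 with an estimated correlation), against 14 and 12 (median −0.05). Of 28 retroelement silencing genes, 20 fell and 3 rose (median −0.64, adjusted p = 8.33e-05, and adjusted p = 0.104 with an estimated correlation), against 12 and 9 (median −0.05). Among single members, the endoplasmic reticulum chaperones HSPA5, HSP90B1 and PDIA4 fell by 1.82, 1.93 and 2.13 (SE 0.09 each), the asparagine synthetase gene ASNS by 1.80 (SE 0.09), the DNA methyltransferase gene DNMT1 by 1.26 (SE 0.09), the MAP kinase phosphatase gene DUSP6 by 1.55 (SE 0.09) and the WNT receptor gene FZD7 by 1.39 (SE 0.09). RPL3, RPS3, HNRNPF and SNRNP70 fell by 0.96, 0.96, 1.91 and 1.54.

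The remaining gene lists were not called against all other genes, though several were in other settings. Of 24 naive pluripotency genes 13 fell and 6 rose (median −0.64), among them KLF17 at −5.83 (SE 0.13), and the list was called lower with TMM factors from genes at 10 CPM or more (adjusted p = 0.00198, and adjusted p = 0.211 with an estimated correlation) and in the refit (adjusted p = 0.00452, and adjusted p = 0.217 with an estimated correlation). It was called lower in 9 of 12 other settings and in 3 of 6 fits with 1 library left out, namely without either hESC_Ctrl_KD library (adjusted p = 0.0464 and 0.0472) and without the second DUX4OE_Ctrl_KD library (adjusted p = 0.0351). For oocyte and maternal genes, 12 of 21 rose and 3 fell (median 1.07). For trophoblast genes, 12 of 19 rose and 2 fell (median 1.74), with GATA2 at 3.60, and the list was called higher with no filter (adjusted p = 0.0458) and without the first DUX4OE_MLT2A1_KD library (adjusted p = 0.0438). Amnion genes rose in 4 of 12 cases and fell in 2 (median 0.03). The medians of 7 lists turned from below to above 0 with TMM factors from genes at 10 CPM or more. These were hypoblast and endoderm (7 of 19 higher and 6 lower, median −0.10 turning to 0.49), mesoderm (3 of 14 higher and 6 lower, −0.15 to 0.44, and then called lower than other genes at an adjusted p of 0.0132, against the sign of its median, and adjusted p = 0.161 with an estimated correlation), neural and ectoderm (6 of 18 higher and 7 lower, −0.39 to 0.19), interferon response (14 of 36 higher and 11 lower, −0.07 to 0.52), heat shock and immediate early genes (10 of 24 higher and 11 lower, −0.01 to 0.58), mitochondrially encoded genes (2 of 13 higher and 8 lower, −0.23 to 0.36) and nonsense-mediated decay (2 of 14 higher and 7 lower, −0.18 to 0.41). Mitochondrially encoded genes were called lower with no filter (adjusted p = 0.0321), without the second DUX4OE_Ctrl_KD library (adjusted p = 0.04999) and without the first DUX4OE_MLT2A1_KD library (adjusted p = 0.0337). Nonsense-mediated decay genes were called lower with no filter (adjusted p = 0.0466), neural and ectoderm genes by limma on both TPM scales (adjusted p = 0.0030 and 0.0027), and mesoderm genes in 5 of 11 settings. The mesendoderm gene EOMES and the Nodal antagonist gene LEFTY1, of the mesoderm list, fell by 3.45 (SE 0.23) and 3.46 (SE 0.13). Adjusted over the list alone, counts were the same in this comparison, except for 27 S phase genes lower and, among heat shock and immediate early genes, 11 higher and 12 lower.

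**Figure D3:**
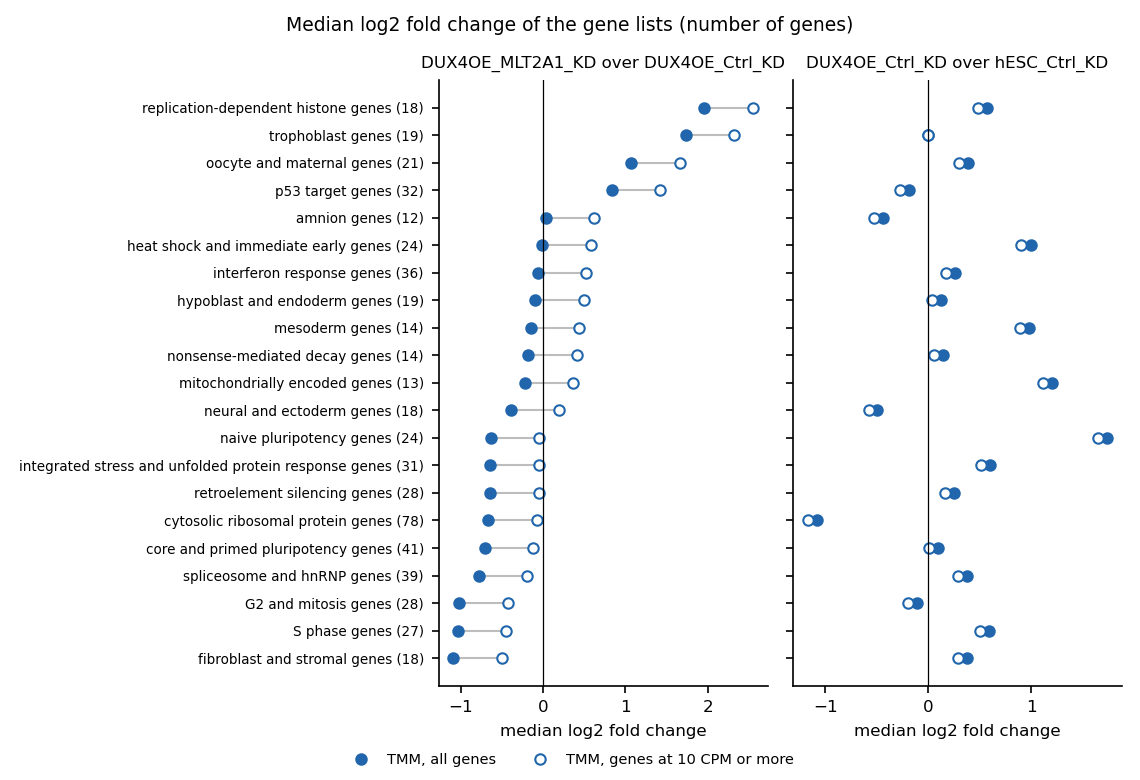
Median log2 fold change of each gene list other than the DUX4 and 8-cell-stage list, with TMM factors from all genes (filled) and from genes at 10 CPM or more (open), for DUX4OE_MLT2A1_KD against DUX4OE_Ctrl_KD (left) and DUX4OE_Ctrl_KD against hESC_Ctrl_KD (right). On the left every median moved up, ribosomal proteins from −0.67 to −0.08 and p53 targets from 0.83 to 1.42; on the right they moved little, ribosomal proteins from −1.08 to −1.17.

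Of single genes, the largest falls in DUX4OE_MLT2A1_KD besides DUX4 were those of DSCR10, TRIM64C, the D4Z4-derived noncoding RNA DBET, PRAMEF6, PRAMEF20, PRAMEF7 and the homeobox gene DUXA. DSCR10 and TRIM64C had no read in the libraries labelled DUX4OE_MLT2A1_KD and were at least 50.4-fold and 47.3-fold lower. DBET fell from 27.2 ± 5.31 to 0.0799 ± 0.113 CPM and DUXA from 186 ± 51.3 to 1.97 ± 0.0637 CPM (log2 fold changes −8.38 and −6.56, SE 0.36 and 0.18). With 1 library left out at a time, the change of DBET ranged from −12.85 to −7.40 and that of PRAMEF20 from −8.75 to −5.95. PRAMEF6, PRAMEF20 and PRAMEF7 fell by 7.63, 6.72 and 6.59, though their reads can be shared among paralogs. The largest rises were in features without a read in DUX4OE_Ctrl_KD. RNU12, a small nuclear RNA of the minor spliceosome, reached 13.5 ± 1.08 CPM, at least 274-fold higher. The U1 variants RNVU1-25 and RNVU1-24, the olfactory receptor gene OR4F17, DIPK2B, FBXO47, DDR1-DT and the adipocyte hormone gene ADIPOQ were at least 221-fold, 149-fold, 151-fold, 134-fold, 120-fold, 114-fold and 102-fold higher.

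Among repeats, MLT2A1 fell and so did the internal sequences ERVL-int and HERVL-int, while most subfamilies, 7 of 10 ERVL internal parts among them, rose. ERVL-int was at 226 ± 13.6 CPM in DUX4OE_Ctrl_KD and 97.3 ± 4.98 CPM in DUX4OE_MLT2A1_KD (−1.22, SE 0.09), and HERVL-int at 781 ± 61.6 and 401 ± 32.2 CPM (−0.96, SE 0.09). The stem cell-expressed HERVH-int fell 2.14-fold (−1.10, SE 0.11, or −0.51 with library sizes alone). Its LTR7 fell by 0.78 (SE 0.09), and was no longer called at −0.18 with library sizes alone. The largest fall was that of the satellite LSAU, part of the D4Z4 array that holds DUX4 genes, from 280 ± 39.0 to 2.90 ± 0.558 CPM (−6.60, SE 0.14), followed by UCON101, MLT1E1-int, Chompy-6_Croc and L1P4b at −2.52, −2.37, −2.20 and −2.19. The satellite HSATI rose from 0.193 ± 0.125 to 14.8 ± 1.27 CPM (6.20, SE 0.32, and 5.66 to 7.07 with 1 library left out). For UCON101 that range was −3.19 to −2.08. SAR, MLT1O-int, UCON92 and MLT1M-int had no read in DUX4OE_Ctrl_KD and were at least 50.5-fold, 26.7-fold, 14.6-fold and 9.27-fold higher.

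By list, 9 of 12 MLT2 LTRs rose and 2 fell, those 2 being MLT2A1 and MLT2A2, the pair that form a list of their own too small to test. Of ERVL internal parts, 7 of 10 rose and 2 fell, and of HERVK and LTR5 4 of 5 rose. THE1 and MST elements rose in 22 of 23 cases, LTR12 in 7 of 7, AluY in 25 of 25 and SVA in 5 of 6. None of these lists was called against the other repeats, and the median over all subfamilies was itself 1.39. Young L1 elements rose in 9 of 9 cases and by more than other repeats (median 1.83, camera adjusted p = 1.48e-04, and adjusted p = 0.787 with an estimated correlation), with L1PA2 at 2.02 (SE 0.09). HERVH and LTR7 lay below other repeats, with 3 of 7 higher and 3 lower (median 0.01, adjusted p = 1.42e-04, and adjusted p = 0.206 with an estimated correlation). For satellites, 12 of 20 rose and 4 fell, and camera placed the list below other repeats although its median, 1.60, lay above theirs (adjusted p = 3.45e-04, and adjusted p = 0.318 with an estimated correlation).

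**Figure D4:**
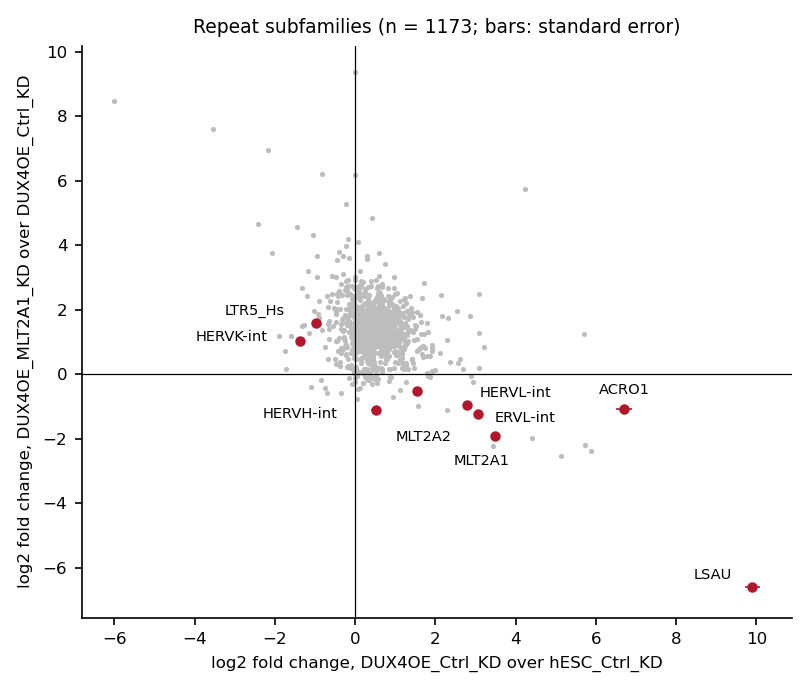
Log2 fold change of 1173 repeat subfamilies with DUX4 induction (horizontal axis) and between the libraries labelled DUX4OE_MLT2A1_KD and DUX4OE_Ctrl_KD (vertical axis), with standard errors for the named ones. Most subfamilies lie above 0 on the vertical axis (median 1.39), while MLT2A1 (vertical −1.91), ERVL-int (3.06 and −1.22), HERVL-int (2.79 and −0.96) and LSAU (9.90 and −6.60) lie at the lower right.

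In all, 13691 of 35375 genes were called higher and 11833 lower in DUX4OE_MLT2A1_KD than in DUX4OE_Ctrl_KD, and 1072 of 1173 repeat subfamilies higher and 30 lower. The split of genes depends on the scaling. Of the called genes 53.6% were higher, but 78.0% with library sizes alone (19192 higher and 5410 lower) and 77.8% with TMM factors from genes at 10 CPM or more (19207 and 5484). The median log2 fold change of all genes moved from 0.17 to 0.76 with either, so directions in this comparison are relative to the scaling. Calls also differed by level. Of the 13691 higher calls, 8380 were of genes with a mean under 1 CPM, part of which passed the filter through the libraries labelled DUX4OE_MLT2A1_KD. Among genes binned by their level in uninduced cells, 32.4% of 7723 at 1 to 10 CPM were higher and 25.5% lower, against 11.6% and 67.0% of 10296 at 10 to 100 CPM and 2.68% and 91.7% of 2280 at over 100 CPM. These shares also depend on the scaling, here TMM factors from all genes. With it, genes with a mean of at least 10 CPM over all libraries had a median log2 fold change of −0.60. That median was −0.004 with library sizes alone and −0.007 with TMM factors from those genes.

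These libraries also held reads over genes that were silent elsewhere. Genes with a read numbered 37236, 37332, 36623 and 35927 in the other 4 libraries and 46587 and 48198 in DUX4OE_MLT2A1_KD. The 12033 genes with at most 2 reads in the other 4 libraries together had 12.7 (95% bootstrap interval 10.9 to 15.3) and 13.9 (12.2 to 16.2) reads per kb of exon in the libraries labelled DUX4OE_MLT2A1_KD where they lay within 10 kb of an expressed gene. Beyond 500 kb they had 0.635 (0.509 to 0.772) and 0.781 (0.623 to 0.951). Mitochondrially encoded transcripts took 4.04% and 3.97% of gene counts in hESC_Ctrl_KD, 6.85% and 6.21% in DUX4OE_Ctrl_KD and 10.2% and 9.36% in DUX4OE_MLT2A1_KD.

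**Figure D5:**
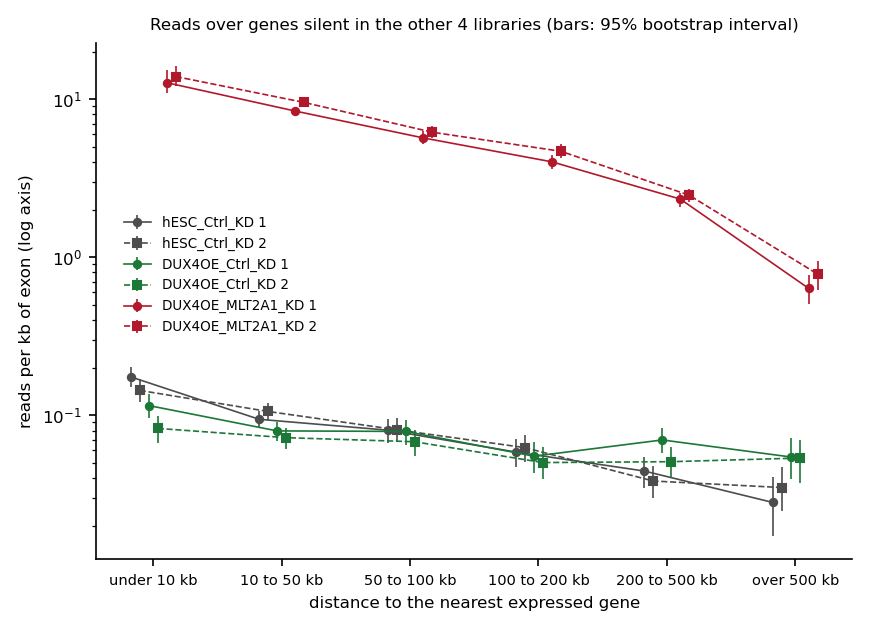
Reads per kb of exon (log axis) over 12033 genes with at most 2 reads in the other 4 libraries together, by distance to the nearest expressed gene, in each library with 95% bootstrap intervals over genes. Genes with under 200 bp of exon and genes that overlap an expressed gene were left out. The 2 libraries labelled DUX4OE_MLT2A1_KD fall from 12.7 and 13.9 within 10 kb to 0.635 and 0.781 beyond 500 kb; the other libraries are low by the choice of genes.

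DUX4 induction was compared between the control groups, DUX4OE_Ctrl_KD and hESC_Ctrl_KD. Only the former was given doxycycline, and no group was labelled as having the drug without DUX4 induction. Effects of doxycycline thus cannot be told apart from those of DUX4. The columns of hESC_Ctrl_KD are also named shNC, and whether its control reagent differed from that of DUX4OE_Ctrl_KD is not known. Effects of such a difference could not be told apart from those of DUX4 either. The same holds for DUX4OE_MLT2A1_KD against hESC_Ctrl_KD. Those groups also differed in the ASO mix, whose effects cannot be told apart there from those of doxycycline and DUX4. DUX4 rose from no read to 348 ± 59.6 CPM, at least 8838-fold, and 8-cell-stage genes rose with it. Of the 75 genes of the list 69 rose and 2 fell (median log2 fold change 11.99, or 9.38 with genes lacking uninduced reads at their bound). For this list camera gave an adjusted p = 3.56e-38, and adjusted p = 0.176 with an estimated correlation. SLC34A2 rose 2728-fold to 1299 ± 84.0 CPM (11.41, SE 0.16), and ZSCAN4 from 0.301 ± 0.0486 to 477 ± 83.8 CPM (1561-fold, 10.61, SE 0.18). The histone demethylase gene KDM4E, TRIM49C, TRIM49 and PRAMEF12 had no uninduced read and rose to 368 ± 17.0, 403 ± 37.1, 397 ± 48.6 and 369 ± 28.8 CPM, at least 9348-fold, 10237-fold, 10080-fold and 9364-fold. TRIM49D2, TRIM49D1 and TRIM64B rose at least 7177-fold, 6915-fold and 6478-fold, and the TRIM49 and TRIM64 copies can share reads. Naive pluripotency genes rose in 14 of 24 cases and fell in 4 (median 1.74, or 1.19 at the bounds). Their adjusted p = 0.00015, and adjusted p = 0.176 with an estimated correlation. KLF17, DPPA3, ALPP and KLF5 rose by 12.92, 8.08, 4.05 and 4.06 (SE 0.23, 0.24, 0.14 and 0.14), DPPA3 by 7.61 to 8.74 with 1 library left out. Mesoderm genes rose in 8 of 14 cases and fell in 2 (median 0.99, adjusted p = 0.0187, and adjusted p = 0.176 with an estimated correlation), with LEFTY1, LEFTY2, EOMES and NODAL at 5.36, 4.61, 7.51 and 2.02. The mesoderm call was lost without either DUX4OE_MLT2A1_KD library (adjusted p = 0.130 and 0.0635), and the median moved to 0.36 without the first of these.

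Core and primed pluripotency genes did not move as a group with induction, with 18 of 41 higher and 16 lower (median 0.09, and 0.00 with TMM factors from genes at 10 CPM or more). The pluripotency factor gene SOX2 fell from 496 ± 26.5 to 166 ± 5.89 CPM (−1.58, SE 0.08) and OTX2, a gene of primed and neural cells, from 127 ± 1.85 to 15.8 ± 0.415 CPM (−3.01, SE 0.10). Among the largest falls were those of the homeobox genes LHX5 and SIX3 and of the signal recognition particle RNAs RN7SL1 and RN7SL2. LHX5 fell from 37.2 ± 1.02 to 0.0156 ± 0.0221 CPM, and its antisense neighbour LHX5-AS1 and PRR15L had no read after induction, at least 168-fold and 61.4-fold lower. Without strand, LHX5 and LHX5-AS1 cannot be told apart where they overlap. NPTX1, SIX3 and CYP26C1 fell by 7.12, 6.69 and 6.41 (SE 0.13, 0.42 and 0.71). With 1 library left out, CYP26C1 ranged from −9.77 to −5.42. RN7SL1 and RN7SL2, which lack a poly(A) tail, fell from 264 ± 59.0 to 1.48 ± 0.124 CPM and from 408 ± 82.8 to 3.19 ± 0.980 CPM (−7.48 and −7.01, SE 0.16 each).

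Cytosolic ribosomal protein genes fell in 74 of 78 cases with induction and rose in 2 (median −1.08, camera adjusted p = 8.34e-30, and adjusted p = 0.176 with an estimated correlation), with RPL12 at −1.76 and RPL37A at −1.85 (SE 0.09 each). Mitochondrially encoded genes rose in 12 of 13 cases (median 1.21, adjusted p = 1.83e-07, and adjusted p = 0.360 with an estimated correlation), MT-CYB from 1299 ± 9.75 to 4824 ± 609 CPM. Heat shock and immediate early genes rose in 18 of 24 cases and fell in 2 (median 1.00, adjusted p = 2.18e-07, and adjusted p = 0.0780 with an estimated correlation), with FOS at 3.86 (SE 0.13) and MYC at 2.48 (SE 0.09). Genes of the integrated stress and unfolded protein response rose in 23 of 31 cases and fell in 3 (median 0.60, adjusted p = 1.99e-06, and adjusted p = 0.0780 with an estimated correlation). Of these the amino acid transporter genes SLC7A5 and SLC7A11 rose by 3.92 and 2.68 (SE 0.12 and 0.09), while DDIT4 fell by 4.16 (SE 0.10). S phase genes rose in 22 of 27 cases and fell in 1 (median 0.59, adjusted p = 8.95e-08, and adjusted p = 0.0780 with an estimated correlation), RRM2 by 2.24 and CCNE1 by 1.62 (SE 0.10 and 0.12). Spliceosome and hnRNP genes rose in 24 of 39 cases and fell in 6 (median 0.38, adjusted p = 1.57e-04, and adjusted p = 0.0986 with an estimated correlation), HNRNPM by 2.01 (SE 0.09). Retroelement silencing genes rose in 15 of 28 cases and fell in 6 (median 0.25, adjusted p = 0.0341, and adjusted p = 0.176 with an estimated correlation), among them the corepressor gene TRIM28 by 0.89 and UHRF1 by 1.49. The call of the last list was lost in 5 of 12 other settings. Among these were TMM factors from genes at 10 CPM or more (adjusted p = 0.0952) and the refit of those genes (adjusted p = 0.285). It was also lost without either DUX4OE_MLT2A1_KD library, where the median stayed at 0.25.

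The other lists were not called with DUX4 induction, except that fibroblast and stromal genes were called higher by DESeq2, with no filter and without the second DUX4OE_Ctrl_KD library (adjusted p = 0.0288, 0.0403 and 0.0343). Higher and lower were 4 and 5 of 21 oocyte and maternal genes, 5 and 1 of 19 trophoblast genes, 5 and 3 of 12 amnion genes, 6 and 2 of 19 hypoblast and endoderm genes and 4 and 5 of 18 neural and ectoderm genes. They were 11 and 5 of 18 fibroblast and stromal genes, 9 and 15 of 32 p53 targets, 11 and 9 of 36 interferon response genes, 6 and 2 of 18 replication-dependent histone genes, 9 and 11 of 28 G2 and mitosis genes and 6 and 4 of 14 nonsense-mediated decay genes. Among them, BTG2 fell by 2.22 (SE 0.13) and SESN2 rose by 1.41 (SE 0.09), the interferon-induced BST2 fell by 3.96 (SE 0.14), KRT7 fell by 3.25 (SE 0.15), and the oocyte growth factor gene GDF9 fell by 1.51 (SE 0.12). Adjusted over the list alone, the counts changed to 70 higher for 8-cell-stage genes, 11 higher for p53 targets, 19 for heat shock, 8 for histones, 23 for S phase, 7 and 5 for nonsense-mediated decay and 1 lower for mitochondrially encoded genes, and were otherwise the same.

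With induction, 760 of 1173 repeat subfamilies rose and 60 fell (median 0.44). By limma on log2(TPM + 1), which tested only features above a minimum mean TPM, 8 rose and 3 fell. MLT2A1 rose 11.3-fold (edgeR adjusted p = 4.65e-19), and by 1.04 in that limma fit, where it was not called (adjusted p = 0.0634). MLT2A2 rose 2.90-fold (1.53, SE 0.10). LSAU rose from 0.290 ± 0.0811 to 280 ± 39.0 CPM (9.90, SE 0.18) and the satellite ACRO1 from 0.316 ± 0.0446 to 33.2 ± 2.52 CPM (6.70, SE 0.20), followed by MLT1E1-int and L1P4b at 5.87 and 5.73. MLT2 LTRs rose in 11 of 12 cases (median 0.66, camera adjusted p = 0.00354, and adjusted p = 0.778 with an estimated correlation), or in 12 adjusted over the list alone. ERVL internal parts rose in 9 of 10 cases (0.70, adjusted p = 7.01e-04, and adjusted p = 0.746 with an estimated correlation) and young L1 in 9 of 9 (1.04, adjusted p = 9.13e-06, and adjusted p = 0.746 with an estimated correlation). HERVK and LTR5 lay below other repeats, with 1 of 5 higher and 2 lower (adjusted p = 0.00457, and adjusted p = 0.746 with an estimated correlation). HERVK-int fell by 1.38 (SE 0.09) and LTR5_Hs by 0.97 (SE 0.09, not called by limma on either TPM scale), and both were higher in DUX4OE_MLT2A1_KD than in DUX4OE_Ctrl_KD, by 1.03 and 1.58 (SE 0.09 each). Between the latter groups the median over all repeat subfamilies was itself 1.39. Not called against other repeats were HERVH and LTR7 (4 of 7 higher, 2 lower), THE1 and MST elements (18 of 23 higher, 1 lower), LTR12 (5 of 7 higher, 1 lower), AluY (16 of 25 higher), SVA (4 of 6 higher, 1 lower) and satellites (8 of 20 higher, 6 lower). Among genes, 8042 rose and 7853 fell of 35375.

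Set against uninduced cells, the libraries labelled DUX4OE_MLT2A1_KD had more reads over 8-cell-stage genes, in part within the range of reads over genes silent elsewhere. Of the 75 genes of that list 68 were higher than in hESC_Ctrl_KD and 4 lower (median 6.60, or 4.49 at the bounds, camera adjusted p = 5.09e-11, and adjusted p = 0.338 with an estimated correlation). In 60 genes the level rose with DUX4 induction, fell in the libraries labelled DUX4OE_MLT2A1_KD and stayed above that of uninduced cells. Of 32 list genes with no uninduced read, at least 500 reads in each DUX4OE_Ctrl_KD library and an annotated exon length, 11 had more reads per kb of exon in both libraries labelled DUX4OE_MLT2A1_KD than 95% of the silent genes within 10 kb of an expressed gene, and 21 did not. MLT2A1 was 1.59 higher than in uninduced cells on the log2 scale, below the median of 1.90 over all repeat subfamilies. In this comparison, ribosomal protein genes were lower in 76 of 78 cases (median −1.71, adjusted p = 6.28e-28, and adjusted p = 0.242 with an estimated correlation), and G2 and mitosis genes in 24 of 28 (−0.99, adjusted p = 6.81e-10, and adjusted p = 0.254 with an estimated correlation). Histone genes were higher in 15 of 18 cases (2.90, adjusted p = 5.69e-05, and adjusted p = 0.228 with an estimated correlation) and p53 targets in 19 of 32, with 7 lower (0.45, adjusted p = 0.0156, and adjusted p = 0.238 with an estimated correlation). Heat shock and immediate early genes were higher in 19 of 24 cases, with 3 lower (0.93, adjusted p = 0.00165, and adjusted p = 0.228 with an estimated correlation), and mitochondrially encoded genes in 12 of 13 (0.88, adjusted p = 0.00105, and adjusted p = 0.461 with an estimated correlation). Core and primed pluripotency genes were lower in 31 of 41 cases and higher in 6 (−0.81, adjusted p = 2.45e-06, and adjusted p = 0.254 with an estimated correlation), a call lost in the refit of genes at 10 CPM or more (adjusted p = 0.259). Naive pluripotency genes were higher in 16 of 24 cases and lower in 5 (1.37, adjusted p = 0.0451, and adjusted p = 0.338 with an estimated correlation). That call was lost in 6 of 12 other settings, among them TMM factors from genes at 10 CPM or more (adjusted p = 0.109). It was also lost without either DUX4OE_MLT2A1_KD library (medians 1.22 and 1.36). S phase, spliceosome and retroelement silencing genes were called lower (adjusted p = 0.00523, 0.00233 and 0.0372, and adjusted p = 0.238, 0.228 and 0.242 with an estimated correlation). Their medians were −0.29, −0.42 and −0.44, which turned to 0.21, 0.09 and 0.07 with TMM factors from genes at 10 CPM or more, where camera no longer called them. Over 12 other settings, this scaling among them, the 3 calls were lost in 6, 5 and 8. Of repeats, young L1 elements lay above other subfamilies (3.01, adjusted p = 4.18e-08, and adjusted p = 0.521 with an estimated correlation). HERVH and LTR7 (0.39, adjusted p = 1.71e-04, and adjusted p = 0.234 with an estimated correlation) and satellites (1.88, adjusted p = 0.0351, and adjusted p = 0.521 with an estimated correlation) lay below them. The other lists were not called in this comparison, but some were in other settings. Fibroblast and stromal genes were called lower in 3 of 12 settings and in 5 of 6 fits with 1 library left out (adjusted p = 0.0547 as reported, and 0.0319 to 0.0470 in those 5). Stress response and nonsense-mediated decay genes were called higher in the refit (adjusted p = 0.0259 and 0.0329, and adjusted p = 0.204 for both with an estimated correlation), neural and ectoderm genes lower by limma (adjusted p = 0.0207 and 0.0263 on the 2 TPM scales), and trophoblast genes higher without the second DUX4OE_MLT2A1_KD library (adjusted p = 0.0493). Apart from the refit and the TMM factors from genes at 10 CPM or more, list calls in other settings were not tested with an estimated correlation. Adjusted over the list alone, 7 spliceosome and 8 silencing genes were higher, against 6 and 7 over all genes, and the other counts were the same. In all, 15143 genes and 1121 repeat subfamilies were higher and 11194 and 16 lower. Of the called genes 57.5% were higher, against 74.9% with library sizes alone (19786 higher, 6648 lower).

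Genes that rose with DUX4 often fell in the libraries labelled DUX4OE_MLT2A1_KD. Of the 8042 that rose with induction, 4755 (59.1%) were lower in the second comparison, against 2690 for independent lists and 3996 for lists independent within 20 bins of mean level, and 1259 were higher in both, against 3112 and 2115. Of the 7853 that fell, 2471 were higher in the second comparison, against 3039 and, within bins, 2171, and 3221 were lower in both, against 2627 and 3586. For genes that fell, the observed counts thus lay on opposite sides of these expected values. The genes with the largest opposite changes were DUX4, DBET, PRAMEF6, DUXA, PRAMEF12, PRAMEF7, LEUTX and PRAMEF2. LEUTX, a homeobox gene of the early embryo on chromosome 19 at 39776595 to 39786167, was without a read in hESC_Ctrl_KD, at 214 ± 52.6 CPM in DUX4OE_Ctrl_KD and at 3.18 ± 0.471 CPM in DUX4OE_MLT2A1_KD. Both comparisons share the libraries of DUX4OE_Ctrl_KD. In 20 simulations of unchanged groups with the same shared libraries, the covariance of log2 fold changes across genes was −0.06, against −1.60 observed (difference −1.54). The simulated overlap of calls was 0, which the adjustment for multiple tests sets when no gene changes, so that it does not bear on the observed overlap. The correlation across genes was −0.32 (simulated −0.51), and genes are not independent replicates. With 1 library of DUX4OE_Ctrl_KD in each comparison and the spread taken from the other groups, a split chosen after seeing the data, 4467 and 4289 genes rose and then fell, against 2392 and 2453 for independent lists. The opposite overlap was 1844 and 1826, below the 2528 and 2593 for independent lists, and the covariance was −1.46 with either assignment of the libraries. The first overlap was 2390 with library sizes alone and 2361 with TMM factors from genes at 10 CPM or more, and the second 4259 and 4438. The calls differed too under these scalings. In the knockdown comparison 5410 and 5484 genes were lower, against 11833 as reported, and 19192 and 19207 higher, against 13691. The expected counts given above therefore do not apply to these overlaps.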

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

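All tests in this part were chosen after the result was seen. Olfactory receptor genes, which form no list compared here and which embryonic stem cells are not known to express widely, had reads far more often in the libraries labelled DUX4OE_MLT2A1_KD than in the control libraries. Of 404 such genes, 70.5% and 74.8% had a read there, against 20.8%, 18.8%, 18.6% and 18.3% in the other libraries.

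More sequencing does not account for it, since the lowest of these shares was still 3.59 times the highest of the others after all libraries were thinned to 42859584 reads. Genomic DNA spread evenly over the genome is excluded as the whole cause, because silent genes within 10 kb of an expressed gene had 17.8 times (95% interval 13.99 to 23.3) the read density of those beyond 500 kb in the library with the lower ratio. Transcription past gene ends may be part of the signal, as density downstream was 1.45 times (1.31 to 1.59) that upstream at 10 to 500 kb in the library with the lower ratio, but within 10 kb, where such reads would be densest, the ratios of 1.07 (0.7499 to 1.45) and 1.13 (0.845 to 1.47) do not show a difference, nor do those beyond 500 kb, at 0.774 (0.515 to 1.197) and 1.03 (0.678 to 1.58). Weaker selection of polyadenylated RNA stays possible, but cannot be told apart here from the rise of silent genes. Of 28 listed RNAs without a poly(A) tail, the 21 tested had a median log2 fold change of 4.23 against uninduced cells (level-matched random lists 0.76). Against DUX4OE_Ctrl_KD it was 3.01 (random lists 0.68). The random lists were matched on the mean over all groups, so they are no baseline for RNAs near the floor in the other libraries. Genes with a mean of 0.1 to 1 CPM had medians of 2.87 and 2.58 in these comparisons. RN7SL1 and RN7SL2 were at −5.95 and −5.53 against uninduced cells, but at 1.52 and 1.48 against DUX4OE_Ctrl_KD. An effect of the knockdown itself stays open and was not tested.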

How the results depend on the processing

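Of the values that answer a comparison, 171 kept their direction and side of the threshold or stayed within 1.5 times the reported count over the alternatives, and 39 did not. The 10 CPM alternatives were chosen after seeing the data. In the knockdown comparison, genes higher numbered 4123 in the refit of genes at 10 CPM or more, which tests fewer genes. Genes lower numbered 5410 with library sizes only, 6525 and 6441 by limma on log2(TPM + 1) and log2(TPM + 0.1), 3984 in the refit, 5484 with TMM factors from genes at 10 CPM or more and 4712 at a log2 fold change of at least 1. Repeats higher numbered 554 and 551 by limma, and repeats lower 13, 8, 8, 8 and 13 with library sizes only, by limma on both scales, in the refit and with those TMM factors. With DUX4 induction, genes higher numbered 4347 in the refit and 3930 at the minimum change, and genes lower 4970 by limma on log2(TPM + 1), 4322 and 3976. Repeats higher numbered 8 and 12 by limma, and repeats lower 3 and 3. MLT2A1 changed by 1.04 by limma on log2(TPM + 1). Against uninduced cells, genes higher numbered 5038 in the refit, and genes lower 6648, 6248, 6136, 4549, 6881 and 5930 in the order given for the knockdown. Genes higher with DUX4 and lower in the knockdown comparison numbered 2390, 2990, 2906, 1735 and 2361 in that order, and the opposite 4259, 1539 and 4438 with library sizes only, in the refit and with those TMM factors. MLT2A2 in the knockdown comparison turned to 0.0640, 0.0634 and 0.0614 with these last 3 settings. The refit changed both the genes tested and the TMM factors, so its moves cannot be put down to either alone. With library sizes only and with TMM factors from genes at 10 CPM or more, only the scaling changed. The median log2 fold change of all genes in the knockdown comparison then moved from 0.17 to 0.76 with either. The added minimum change is a stricter rule, and for the other moves the cause was not tested. Of single genes and repeats, 2034 values were the same, 9 lost the call over 4 results (HERVH-int and LTR5_Hs with induction, LTR7 and ACRO1 in the knockdown comparison) and 3 reversed. With 1 library left out at a time, the remaining library of its group being assumed to vary like the other groups, no count moved by over 1.5 times: genes ranged from 10388 to 14255 higher and 11336 to 11767 lower in the knockdown comparison, and from 5805 to 7932 and 5743 to 8038 with induction. The replicate numbers did not pair the samples (correlations −0.00587, −0.00985 and 0.00723), and the replicate block gave 12747 genes higher and 11792 lower in the knockdown comparison and 7785 and 7739 with induction. The block also ended the list calls of mesoderm genes with induction (adjusted p = 0.0745) and of naive pluripotency genes against uninduced cells (adjusted p = 0.0646), and of no other gene list. Genes with few reads in a group, such as DBET and LHX5, are limited by depth.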

Other observations

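The tests in this part were chosen after the results were seen. Over the 12419 genes with a mean of at least 10 CPM, fitted with their own TMM factors, 71 families of genes that share a name stem were compared with all other genes by camera. Zinc finger genes named ZNF were higher in the libraries labelled DUX4OE_MLT2A1_KD than in DUX4OE_Ctrl_KD, with 257 of 361 higher and 32 lower (median 0.64, adjusted p = 3.04e-11, and adjusted p = 0.848 with an estimated correlation). In the refit of these genes together with repeats at that level, 4123 of all 12419 genes were higher and 3984 lower. Families were not matched on level, with which calls in this comparison differed, so a shift particular to ZNF genes was not tested. With DUX4 induction, 17 of 20 COX genes, most of them parts of mitochondrial cytochrome c oxidase, were lower and 1 higher (median −0.84, adjusted p = 1.72e-04), while 19 of 21 nucleoporin genes named NUP (median 0.53, adjusted p = 0.0138) and 11 of 15 DHX helicase genes (median 0.68, adjusted p = 0.0174) were higher. With an estimated correlation, each of these 3 families had an adjusted p = 0.900. Other families were called too. TRIM genes lay below other genes in DUX4OE_MLT2A1_KD (14 of 48 higher and 23 lower, adjusted p = 6.81e-12, and adjusted p = 0.486 with an estimated correlation), as did COL genes (5 of 22 higher and 16 lower, adjusted p = 0.0363, and adjusted p = 0.848 with an estimated correlation). With induction TRIM (26 of 48 higher and 10 lower, adjusted p = 1.17e-22, and adjusted p = 0.118 with an estimated correlation) and ZSCAN (5 of 15 higher and 7 lower, adjusted p = 0.00308) lay above other genes, and MIR (6 of 30 higher and 17 lower, adjusted p = 0.0174), RPL and RPS below. For these last 4, an estimated correlation gave an adjusted p = 0.900. The ZSCAN call went against the counts of that family, of which more genes were lower than higher. TRIM, ZSCAN, COL, RPL and RPS genes include members of the fixed lists.

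DUX4 was almost without reads in the libraries labelled DUX4OE_MLT2A1_KD. Cells that were never induced, with nothing but the reads found over silent genes, are argued against, as 11 of 32 8-cell-stage genes without an uninduced read and with at least 500 reads in each DUX4OE_Ctrl_KD library lay above the 95th percentile of silent genes near expressed genes (58.1 and 66.1 reads per kb) in both libraries. Carry-over from the DUX4OE_Ctrl_KD libraries as the whole source of that excess is argued against too, as the 32 genes had 3512 and 3506 reads, at least 1.45 times the 2114 and 2417 that the upper end of the 95% range of sums over random silent genes and carry-over at 0.410% and 0.543%, the upper limits set by DUX4 and DUX4-like features, would give. Neither is excluded in a stricter form, with the 95th percentile taken off at each of the 32 genes, a background that 144 and 137 of 10000 random sums reached. The summed level of the 32 genes was then 0.468% (95% bootstrap interval −0.666 to 1.25) and 0.188% (−1.02 to 0.988) of control. Both intervals include no excess at all, and also the carry-over limits of 0.410% and 0.543%. The random silent genes were drawn independently, while PRAMEF, TRIM49 and other paralogs among the 32 genes can share reads. Background over the 32 genes may therefore vary more than over the random genes, which weakens both arguments. Whether the fall of 66 list genes followed the loss of DUX4 or of MLT2A1 cannot be told apart, since both were lower in the same libraries, and a direct effect of the MLT2A1 ASO mix on DUX4 transcripts was not tested.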
